A study of Drosophila melanogaster with 62 samples.

How the data were processed

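Total RNA from 56 samples of 20 hand-sorted embryos each and nuclear RNA from 6 samples of 300 embryos each had been sequenced. The authors deposited raw counts per FlyBase gene, for total and nuclear RNA, without normalisation. Reads were demultiplexed with bcl2fastq 2.20.0.422 and assigned to genome build dm6, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. The tables held 17753 genes, of which 17626 (99.3%) matched an identifier of Ensembl release 115, and 92 ERCC transcripts in nuclear RNA. Coordinates are those of that release (dm6). Groups followed the sample titles, and all 62 libraries were used. One HDAC6 library has conflicting stage fields and was kept at the stage of its title.

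Genes were filtered with filterByExpr (10 counts, 15 in total) and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood F test, adjusted p under 0.05 by Benjamini and Hochberg over all genes tested). At each stage the 5 groups of the main set were fitted together, as were the 3 groups of batch1. The stage comparisons of controls, the rescue pairs and the nuclear groups were fitted alone. The effect of a knockdown at stage 5 minus that at stage 2 was tested as an interaction in a fit of both stages of the main set. Nuclear libraries were scaled to the sum of their ERCC counts, as the labels state that the spike-in was added to correct for global changes in RNA. CPM are counts per M counts of the scaled library, and for nuclear RNA the library size was the ERCC sum scaled to the mean fly total. Levels compared across sets, and those plotted, were scaled by TMM over all total RNA libraries, and levels beside a fold change within its own fit. The standard error is the log2 fold change divided by the normal quantile of its p. These errors carry the spread between samples as well as depth, and the lowest total RNA library had 2.45 M counts. The p-values measure the spread between samples, which may be technical. Where a group had 0 counts, 3 counts over the group served as a floor and the fold is a lower bound.

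22 gene lists were written from general knowledge before the data were examined: gap, pair-rule, segment polarity, homeotic, mesoderm, neuroectoderm, dorsal ectoderm, early zygotic and cellularization genes, maternal axis, maternal regulators, germ plasm and piRNA genes, acetyltransferases and SAGA, deacetylases, histone variants, chorion, vitelline and yolk genes, late neural and muscle genes, other late genes, testis, heat shock, apoptosis and p53, immune and ribosomal protein genes. 4 lists came from the stage comparison of the control set not used in the comparison at hand: zygotic (stage 2 CPM under 1, log2 rise of at least 3), maternal-zygotic (CPM of at least 1, rise of at least 1), cleared (fall of at least 1) and stable (change under 0.5, CPM of at least 5). A list needed 3 measured members. Lists were tested with camera of limma 3.58.1 (preset correlation of 0.01, then an estimated one) and with fry, and adjusted over the lists of a comparison. Members were also adjusted over the list alone.

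The genes named were set by a rule fixed before the data were examined. It takes the targets, the 8 largest rises and falls (5 for stage 2, direct, interaction and batch1 comparisons) among genes that passed with at least 5 CPM in the higher group and no overlap between the libraries of both groups (chance gives 10% for 3 against 3), without genes known only by an identifier and noncoding genes, then up to 4 members per list with the lowest adjusted p, and a fixed panel at stage 5 (Kr, kni, eve, ftz, sna, twi, zen, sog, dpp, en, sc, zld, bcd, nanos and Hsp83). Of 437 genes named by the rule, 12 share over 0.5 of their exons with another gene (Antp, Dark, Dhit, HDAC3, Irk1, RpS9, Sirt4, Srx, Trl, armi, grim and osk). Their counts, and those of Hsp70 and histone copies with near-identical sequence, are uncertain. A gene that the rule names between the Nejire rescues is not reported here.

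The alternatives were RLE scaling, scaling to the stable list, TMM on fly genes or among ERCC transcripts for nuclear RNA, no filter of low counts, a fit of the 2 groups alone, a replicate block, DESeq2 1.42.0, stricter list limits, only the 3 controls named for the Enok and HDAC6 knockdowns, and each library left out in turn. Comparing stage 5 knockdowns of the main set with the batch1 controls was added after the data had been seen. Counts with known changes were simulated to test recovery: of 200 changed genes per comparison, 50 for each size and direction, those of 2 log2 units were recovered in 100% (Nejire knockdown, falls, of 7653 genes) and those of 1 unit in 84%. An axis of embryo age was taken as the main component of the 6 Gcn5 rescue libraries after their group means were removed, signed so that the cleared list falls along it, and was chosen after the data had been seen. Correlations between comparisons that share controls were set beside 100 simulated draws without effects. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.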

Results

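RNA was sequenced from Drosophila melanogaster embryos in which 1 of 6 enzymes that set or remove histone acetylation had been knocked down. Nejire (the fly CBP), Gcn5 and Enok are lysine acetyltransferases, and HDAC1, HDAC3 and HDAC6 are deacetylases. Embryos were collected at stage 2, when the embryo runs on RNA loaded by the mother, and at stage 5, the cellular blastoderm, when its own genome is widely transcribed. The 62 libraries formed 22 groups, with 3 libraries in 16 groups, 2 in 5 groups and 4 in 1 group. Nejire, Gcn5, HDAC1 and HDAC3 knockdowns shared 1 set of controls (here the main set). Enok and HDAC6 knockdowns had controls of their own, in a set that the labels call batch1. These pool controls that the library names call Ctrl-KD and CtrlAc-KD, of the same cross. By the library names each knockdown had a parent line of its own, and the main and batch1 controls shared another. Knockdown and line therefore cannot be told apart in any comparison with these controls. At stage 5 the series also held embryos that carried wild type or catalytic dead Nejire or Gcn5 as a rescue. Nuclear RNA of Nejire knockdown embryos, and of controls whose library names say wild type, was sequenced with ERCC spike-in transcripts. Each total RNA library came from 20 embryos and each nuclear library from 300 embryos. Total counts per library ran from 2.45 to 40.4 M for total RNA and from 14.8 to 20.7 M for nuclear RNA.

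The targeted genes were examined first, as a check of the labels. nej (FBgn0261617, X, 9665442 to 9687066, minus strand) was measured at 98.5 ± 13.2 CPM against 337 ± 156 (Nejire knockdown against control) at stage 2 and at 264 ± 79.9 CPM against 1026 ± 537 at stage 5 (normalised CPM, mean ± SD, n = 3). The fitted change of nej was -1.78 ± 0.39 (adjusted p = 2.2e-04) at stage 2 and -1.96 ± 0.45 (adjusted p = 1.2e-04) at stage 5, as log2 fold ± standard error. In nuclear RNA, nej was measured at 555 ± 648 CPM against 3025 ± 898, a change of -2.45 ± 0.94 that did not pass (adjusted p = 0.0637), and the 3 knockdown libraries lay between 147 and 1303 CPM. Gcn5 (FBgn0020388, 3L, 12521129 to 12524014, minus strand) fell by the most at stage 2, from 144 ± 2.79 to 0.153 ± 0.187 CPM, and at stage 5 from 236 (n = 3) to 33.0 CPM (n = 2). HDAC1 (FBgn0015805, 3L, 4626734 to 4629467, plus strand) changed by -7.72 ± 0.90 at stage 2 and -2.17 ± 0.29 at stage 5. enok (FBgn0034975, 2R, 24099210 to 24107032, plus strand) changed by -5.25 ± 0.70 and -2.21 ± 0.39, and HDAC6 (FBgn0026428, X, 15333310 to 15340360, plus strand) by -6.96 ± 1.02 and -1.48 ± 0.31. Each target was below every control library in every knockdown library of its own, at both stages. HDAC3 (FBgn0025825, 3R, 5472810 to 5474600, minus strand) had 0 counts in all 62 libraries, as did CG45100, annotated over the same span, so the HDAC3 knockdown could not be checked. The HDAC6 library labelled stage 5 in its title and stage 2 in another field carried zygotic transcripts at the level of the other stage 5 libraries. In the rescues, nej ran from 3450.0 to 4155 CPM and Gcn5 from 6841 to 9589 CPM, far above the controls. nej, with 15932 bases of exon, also fell in Gcn5 knockdown (-1.48 ± 0.44) and in HDAC1 knockdown (-1.24 ± 0.38) at stage 5. Both changes ran against gene length (Spearman -0.329 and -0.175 across genes), and the control with most nej, replicate 1, had the steepest rise with length (0.27 in log2 CPM per doubling).

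**Figure D1:**
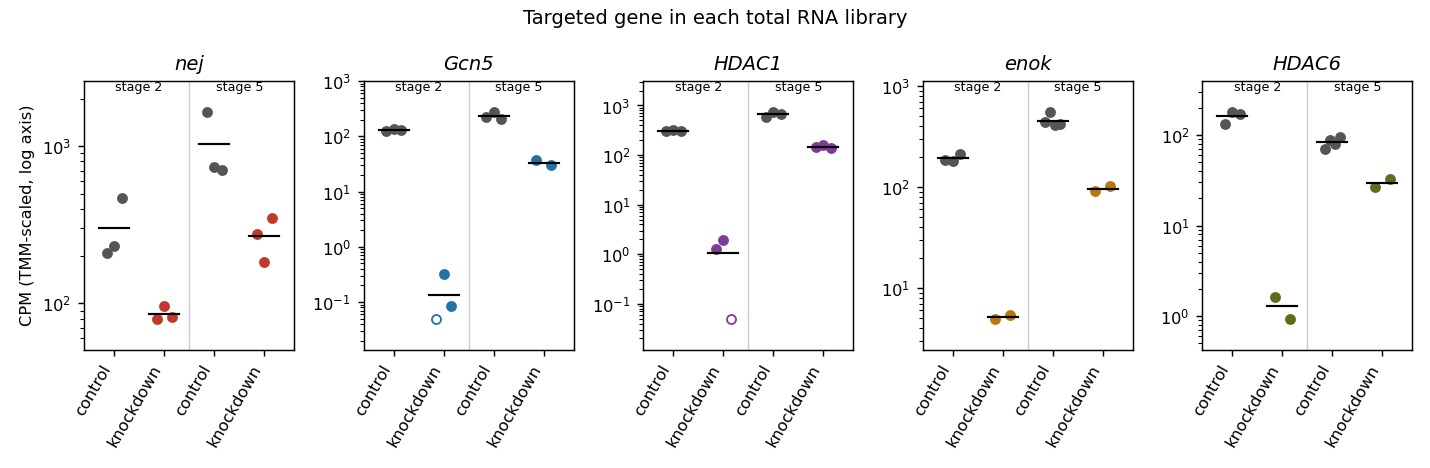
Level of each targeted gene in every library of its own knockdown and control groups, in CPM on a log axis (points, libraries; bars, group means; open circles at the bottom, 0 counts). Knockdown libraries of nej at stage 5 sit between 184 and 348 CPM, below all main set controls (707 to 1649.5).

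Control embryos of both sets were compared between stages to measure the handover from maternal to zygotic RNA. Gap gene knirps (kni), mesoderm regulator snail (sna), fushi tarazu (ftz), Kruppel (Kr), short gastrulation (sog), decapentaplegic (dpp) and twist (twi) were at or near 0 counts at stage 2 and all rose. The most abundant new transcripts included Mdr49, an ABC transporter, at 730.1 ± 135 CPM, and Inx3, an innexin, at 707 ± 112 CPM. Among maternal transcripts, deadhead (dhd), a thioredoxin of the egg, changed by -6.79 ± 1.04 (34.7 ± 6.17 CPM against 3776 ± 194), exuperantia (exu), needed to localise bicoid RNA, by -5.60 ± 0.86, nanos by -3.75 ± 0.64 and Hsp83 by -3.48 ± 0.59. The glutathione transferase GstD1 (-7.46 ± 1.12) and the cytochrome P450 gene Cyp6a19 (-8.63 ± 1.31) were cleared as well. bicoid (bcd) itself changed by -0.55 ± 0.27 in the main set and did not pass (adjusted p = 0.0507), but by -4.52 ± 0.60 in batch1, from 128 ± 8.42 to 5.4 ± 1.31 CPM. zelda (zld), the pioneer factor of zygotic genes, rose by 2.14 ± 0.57. In the main set 5929 of 7428 genes changed (3155 rose, 2774 fell), and in batch1 6863 of 7872 (3850 rose, 3013 fell).

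The lists fixed before the data were examined were followed between the stages in the main set. Rises were called for 13 of 14 gap genes, 11 of 11 pair-rule genes, 8 of 8 segment polarity genes, 18 of 18 dorsal ectoderm genes and 19 of 19 early zygotic genes, with the same counts adjusted over the list alone. In these lists camera's adjusted p ran from 0.0935 (gap genes, among others) to that of segment polarity genes (0.153) with an estimated correlation, under which no list was called. Acetyltransferase and SAGA genes went both ways (18 rose, 6 fell), as did deacetylase (10 and 5), histone variant (4 and 2) and heat shock genes (1 and 5). Of the maternal regulators of the egg, 14 of 18 fell (adjusted p = 0.453 with an estimated correlation), and of the germ plasm and piRNA genes 15 of 20 fell (adjusted p = 0.271 with an estimated correlation). Ribosomal protein genes rose in 58 of 81 cases (median 0.48), though camera did not call them as a list (adjusted p = 0.0767). From batch1, 1190 genes formed a zygotic list, 1076 a maternal-zygotic list, 2039 a cleared list and 1559 a stable list. These lists were used on the main set and on nuclear RNA, and their counterparts from the main set on batch1. In the main controls 789 of the 1190 zygotic genes passed the filter, and all 789 rose. As these genes are low at stage 2, the filter keeps nearly only those high at stage 5, which largely fixes that outcome. Of the other lists, 996 of 1072 maternal-zygotic genes rose, 1864 of 2036 cleared genes fell, and the stable list went both ways (444 rose, 402 fell).

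Nejire knockdown at stage 5 asked which transcripts depend on this acetyltransferase once the zygotic genome is active. Segmentation and dorsoventral patterning genes fell together. The gap gene Kr fell from 323 ± 33.0 to 68.8 ± 3.91 CPM (-2.23 ± 0.29, adjusted p = 2.0e-11), the pair-rule genes odd-paired (opa) by -2.89 ± 0.45 and even skipped (eve) by -2.38 ± 0.43, and the homeotic gene Antennapedia (Antp) from 41.9 ± 6.12 to 3.32 ± 1.03 CPM (-3.73 ± 0.52, adjusted p = 1.5e-10). tolloid (tld), a protease that releases the morphogen Dpp, fell from 349.6 ± 43.8 to 49.9 ± 5.33 CPM (-2.81 ± 0.37, adjusted p = 2.1e-11), and dpp itself changed by -2.36 ± 0.35. Changes of wingless (wg, -2.51 ± 0.39), the FGF ligand thisbe (ths, -2.81 ± 0.39), the FGF receptor heartless (htl, -2.48 ± 0.38) and the amnioserosa factor Doc1 (-2.93 ± 0.40) were of like size. Smaller falls were measured for twi (-1.66 ± 0.31), sna (-1.41 ± 0.26), kni (-1.33 ± 0.27) and zld (-0.86 ± 0.30). engrailed (en) changed by -0.98 ± 0.52 (adjusted p = 0.123) and Hsp83 by -0.25 ± 0.15 (adjusted p = 0.158), and neither passed.

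By list, 11 of 11 pair-rule genes fell (median -2.31, adjusted p = 0.00334 with an estimated correlation), and 7 of 7 homeotic genes (median -2.95, 0.0475). Dorsal ectoderm genes fell in 17 of 19 cases (19 when adjusted over the list alone, median -2.36, adjusted p = 9.1e-04 with an estimated correlation). Mesoderm (12 of 14; 13 adjusted over the list alone), neuroectoderm (12 of 14; 12) and segment polarity genes (5 of 8; 6) fell too, and their calls held with an estimated correlation (adjusted p = 0.00773, 0.012 and 0.00838). Of the early zygotic genes 16 of 19 fell (adjusted p = 0.0475 with an estimated correlation). For the gap genes, 11 of 14 fell, but the list's call was lost (adjusted p = 0.0975 with an estimated correlation). No member of these 8 lists rose. Of the zygotic list, 666 of 1134 genes fell and 22 rose (714 and 27 adjusted over the list alone), with a median of -1.58 and an adjusted p = 0.00334 with an estimated correlation. The maternal-zygotic list fell in 330 of 1076 cases.

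Maternal transcripts were examined next in the Nejire knockdown. bcd rose by 0.90 ± 0.30 to 161 ± 17.9 CPM (control 85.6 ± 36.7), the phosphatase gene twine (twe) by 0.89 ± 0.25, the pole cell gene pgc by 1.26 ± 0.26 and oskar (osk), which shares most of its span with a noncoding gene, by 1.02 ± 0.32. Of the maternal regulators, 9 of 18 rose (adjusted p = 0.383 with an estimated correlation), of the germ plasm and piRNA genes 8 of 20 (10 adjusted over the list alone, adjusted p = 0.363 with an estimated correlation), and of the maternal axis genes 7 of 17, not a call for the list (adjusted p = 0.198). The cleared list rose in 518 and fell in 250 of 1996 cases. The largest rises were those of Hsp70Bb, a stress-induced chaperone with near-identical copies (6.78 ± 1.06), Cyp4p2 (5.96 ± 0.87), the cell adhesion gene Dscam4 (5.42 ± 0.78), the dopamine transporter DAT (5.25 ± 1.25) and the glutamate receptor subunit GluRIIB (4.79 ± 0.94). In the Nejire rescues, of another set and other parent lines, 3 of these stayed above the controls. With the wild type protein Hsp70Bb, Cyp4p2 and Dscam4 stood at 18.7, 23.7 and 34.6 CPM, against 0.21, 0.384 and 0.682 in the controls. Dscam4 rose in all 6 knockdowns. Mean Hsp70Bb levels at stage 5, on the same scale, were also 23.2 CPM without Enok, 13.1 without HDAC6, 6.49 without HDAC3 and 5.25 without HDAC1. Gcn5 knockdown had 0.84 CPM and the batch1 controls 0.173, so the rise of Hsp70Bb is not particular to Nejire. Among the largest falls were Egfrap (-5.70 ± 0.92), the phosphatase Alp1 (-5.35 ± 0.90), the serotonin receptor 5-HT2A (-4.41 ± 0.67) and Cyp18a1, which inactivates ecdysteroids (-4.33 ± 0.82). Of the apoptosis and p53 genes, 7 of 14 fell, among them reaper (rpr, -2.66 ± 0.46), and 4 rose (adjusted p = 0.113 with an estimated correlation).

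Across the genome, 3124 of 8236 genes changed: 1324 rose and 1800 fell, of which 247 and 1156 changed at least 2-fold. Against the batch1 controls 2966 calls had the same and 13 the opposite direction. Scaled to the stable list, all genes shifted by a median of -0.18 and the split became 660 up and 2428 down. Ribosomal protein genes then turned from a median of 0.17 (4 of 82 rose, 0 adjusted over the list alone, adjusted p = 0.65 with an estimated correlation) to -0.01.

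**Figure D2:**
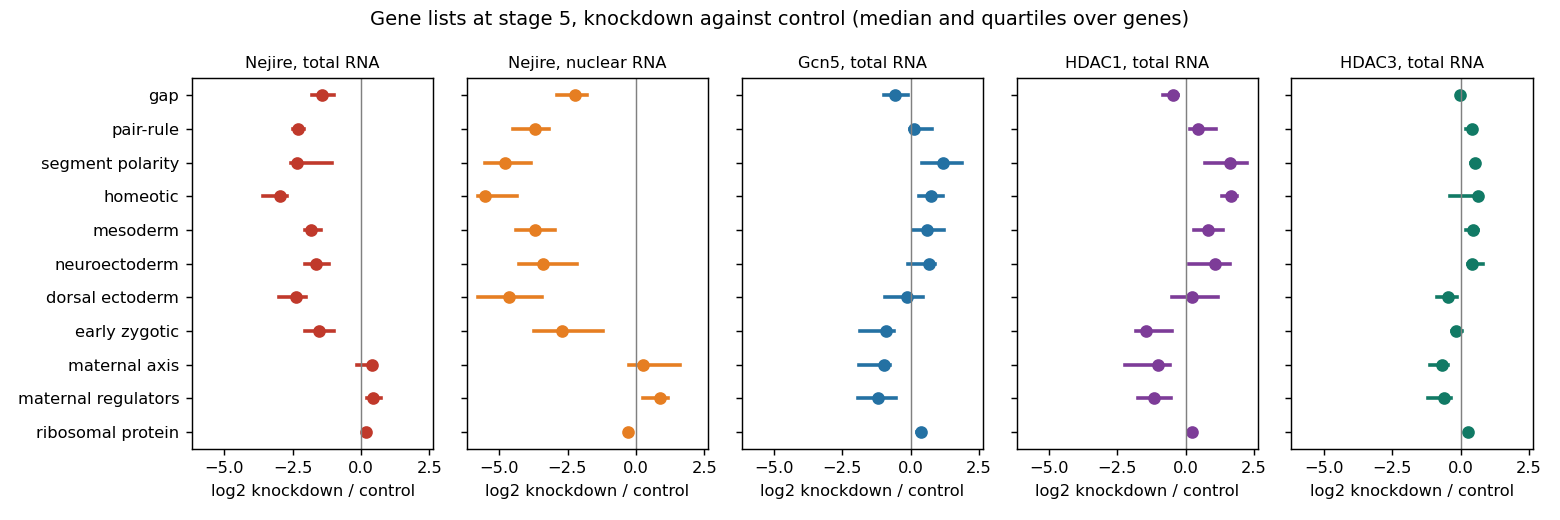
Log2 fold change against the matched control for the members of the fixed lists at stage 5 in 5 knockdown or nuclear comparisons (points, median over a list's genes; bars, lower to upper quartile over genes). The Nejire knockdown medians of the patterning lists lie left of 0 (pair-rule -2.31), and the HDAC1 knockdown medians lie right of 0 for segment polarity (1.62) and left of it for early zygotic genes (-1.44).

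**Figure D3:**
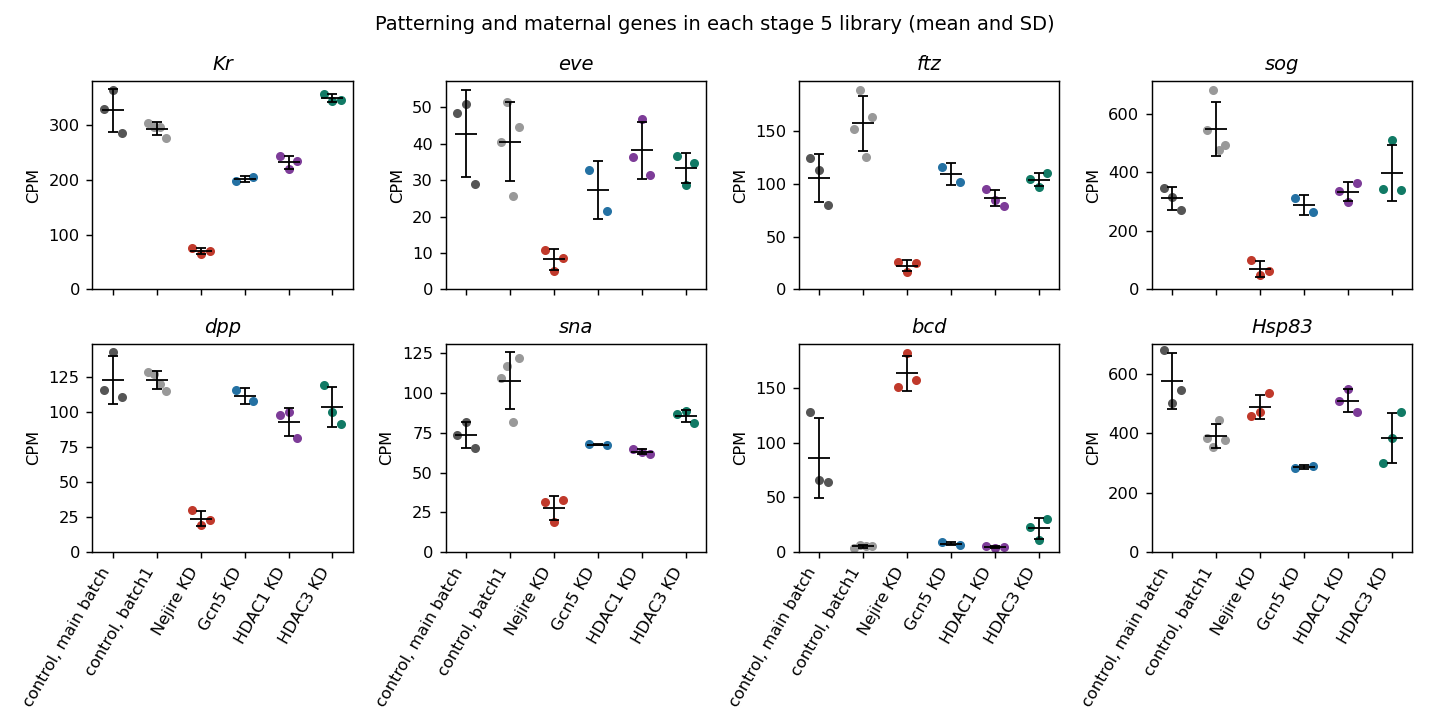
Levels of 8 genes in each stage 5 library of 6 groups, in CPM, with the group mean and SD. Kr and sog are lowest in Nejire knockdown, and bcd is high in Nejire knockdown and low in Gcn5 knockdown, HDAC1 knockdown and the batch1 controls.

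Nuclear RNA was compared between Nejire knockdown and control embryos to look closer at transcription, with libraries scaled to their ERCC counts. The library names call these controls wild type, not the control knockdown of total RNA. Within nuclear RNA, as in total RNA, loss of Nejire and fly line therefore cannot be told apart. The homeobox gene C15 changed by -7.35 ± 1.23, the T-box gene Doc2 by -6.68 ± 0.99, the COE factor knot (kn) by -6.72 ± 1.06, Antp by -6.04 ± 1.00, wg by -5.51 ± 0.94 and en by -5.50 ± 0.94 (n = 3 and 3). Kr changed by -3.60 ± 0.93, ftz by -3.72, sog by -3.37, eve by -3.05 and sna by -2.85 on the log2 scale. The adhesion gene DIP-theta fell from 45.4 ± 1.01 to 0.109 ± 0.103 ERCC-scaled CPM (-9.02 ± 1.15, adjusted p = 2.6e-11) and the nuclease gene DNaseII from 324 ± 62.0 to 2.14 ± 0.831 (-7.26 ± 1.06). kni (-2.05 ± 0.85, adjusted p = 0.0947), zld (-0.81 ± 0.90, adjusted p = 0.737) and bcd (1.96 ± 0.85, adjusted p = 0.118) did not pass. Rises were called for Hsp70Bb (10.61 ± 1.29), the sulfotransferase St3 (8.38 ± 1.37), the stress factor Xrp1 (3.17 ± 0.83) and osk (2.70 ± 0.91).

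All 11 measured pair-rule genes, 7 of 8 segment polarity, 6 of 7 homeotic, 12 of 14 mesoderm and 18 of 19 dorsal ectoderm genes (19 adjusted over the list alone) fell in nuclear RNA. Neuroectoderm genes fell in 10 of 14 cases, early zygotic genes in 10 of 19 and gap genes in 6 of 14, or 13, 12 and 11 adjusted over the list alone. Camera called all 8 lists with the preset correlation and none with an estimated one (adjusted p from 0.505 for dorsal ectoderm to 0.748 for gap genes with an estimated correlation). The zygotic list fell in 572 of 1168 cases (679 adjusted over the list alone, median -2.40, adjusted p = 0.608 with an estimated correlation). Eggshell genes of the mother's follicle cells were measured in nuclear RNA (9 genes; psd rose, Cp36 and dec fell), as were testis genes (4; topi fell). Of the late neural and muscle genes 3 of 8 fell and of the other late genes 5 of 14, with 1 rise (Ppn).

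In all, 1248 of 9295 genes changed in nuclear RNA (327 rose, 921 fell). The ERCC counts per M fly counts were 282, 284 and 69.5 in the knockdown libraries and 98.5, 100.0 and 134 in the controls, and on simulated changes of 2 log2 units the scaled test recovered 4% of falls and 2% of rises (50 genes each, of 8715). With TMM on fly genes 5626 genes were called, 2769 up and 2857 down, and all genes shifted by a median of 0.29. With 1 library left out the ERCC-scaled count was 7272 without knockdown replicate 3, 1439 and 801 without replicates 1 and 2, and 548, 560 and 593 without control replicates 1, 2 and 3, and a replicate block gave 716.

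Total and nuclear effects of the Nejire knockdown were set side by side over 8088 genes measured in both. They shared no library, and across genes, which are not independent replicates, they correlated with r = 0.817 (Spearman 0.793). Of the genes called in both, 773 moved the same way (691 down, 82 up) and 2 opposite ways, where independent lists would share 168 down and 20.3 up.

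The Nejire rescues asked whether the catalytic activity of Nejire matters, as wild type against catalytic dead protein within 1 set of libraries. rdgB, a phosphatidylinositol transfer protein, was lower with the wild type protein (-1.37 ± 0.28, adjusted p = 0.00147), as was Rbcn-3A (-0.64 ± 0.14). The dynein heavy chain Dnah3 (2.28 ± 0.50), the Wnt inhibitor Notum (0.56 ± 0.14) and the Sox factor Dichaete (D, 0.34 ± 0.08) were higher. edgeR called 21 of 8139 genes (13 higher and 8 lower with the wild type protein), 1222 had an unadjusted p under 0.05 (chance gives 5% of genes), and DESeq2 called 88. Without a filter of low counts 478 were called, and with 1 library left out from 7 (wild type replicate 2) to 145 (catalytic dead replicate 1). A replicate block called fewer than the 21 of the main fit. nej itself differed by 0.04 ± 0.06 (adjusted p = 0.784). Of the early zygotic genes 0 of 18 passed over all genes and 8 were higher and 1 lower when adjusted over the list alone (adjusted p = 0.375 with an estimated correlation), and in the zygotic list 3 of 952 were higher. The genes that fell in the knockdown had a median of -0.06 between the rescues (camera adjusted p = 0.0186, p = 0.599 with an estimated correlation), and those that rose a median of 0.04 (0.0186, p = 0.55 with an estimated correlation).

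No knockdown or control library belonged to the rescue sets, so rescue and set cannot be told apart in comparisons across them. By the library names the Nejire rescues also came from other parent lines than the Nejire knockdown, so line cannot be told apart either. The zygotic list had a median of -1.46 in Nejire knockdown minus control in the joint fit. It stood higher than the knockdown by 0.80 with the wild type protein (520 of 1190 genes rose, 94 fell) and by 0.94 with the catalytic dead protein (565 rose, 68 fell). Both rescues stayed below the main set controls (medians -0.59 and -0.49), and the control sets alone, batch1 minus main, differed by 0.87 (635 rose, 47 fell). For Gcn5 the rescues lay below the knockdown by a median of -0.53 with either protein.

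Gcn5 knockdown at stage 5 asked the same of the second acetyltransferase. Of 31 acetyltransferase and SAGA genes 9 fell, among them Spt20 (-1.44 ± 0.30), Ada2b (-1.08 ± 0.23) and Br140, a partner of Enok (-1.46 ± 0.28), and 6 rose. Ryanodine receptor RyR fell from 17.6 ± 3.02 to 0.758 ± 0.505 CPM (-4.49 ± 0.78, adjusted p = 6.7e-07, n = 2 and 3), tld by -1.51 ± 0.25, the early gene spri by -1.59 ± 0.26 and zld by -1.29 ± 0.37. The pigmentation gene yellow (y) rose from 2.37 ± 1.16 to 152 ± 29.5 CPM (5.88 ± 0.86, adjusted p = 1.2e-08), the odorant receptor Or2a by 6.25 ± 1.12, the eggshell genes Cp15 and Cp18 by 7.87 ± 1.72 and 5.41 ± 1.32, Dscam4 by 5.69 ± 0.81 and Cyp4p2 by 5.17 ± 0.81. In the Gcn5 rescues, another set, y stood at 128 CPM with the wild type and 134 with the catalytic dead protein, Cyp4p2 at 61.3 and 69.4, and Dscam4 at 50.0 and 50.0, so none of these was back at the control level. Ribosomal protein genes rose in 50 of 82 cases (54 adjusted over the list alone, median 0.38, RpL23 0.78 ± 0.19), with an adjusted p = 0.544 with an estimated correlation. Over all genes the change ran against gene length (Spearman -0.329 across genes). The genes named here kept their direction and call against the batch1 controls, a comparison across sets that was chosen after the data were seen.

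For some other gene groups the direction depended on the control set. The maternal gene bcd, scaled over all total RNA libraries, stood at 7.77 ± 1.42 CPM in Gcn5 knockdown (n = 2), 86.1 ± 36.4 in the main controls (n = 3) and 5.25 ± 1.27 in the batch1 controls (n = 4). Against the main controls bcd changed by -3.48 ± 0.63, the translational repressor smaug (smg) by -3.23, nullo, a gene of cellularization, by -4.88 and the Dorsal target zerknullt (zen) by -1.64 on the log2 scale. The late patterning genes gooseberry (gsb, 2.47 ± 0.54), single-minded (sim, 2.23 ± 0.46), hedgehog (hh, 1.96 ± 0.40) and Ultrabithorax (Ubx, 1.60 ± 0.36) rose. Of the maternal regulators 15 of 18 fell, of the maternal axis genes 14 of 17, and of the early zygotic genes 14 of 19 (adjusted p = 0.32, 0.32 and 0.356 with an estimated correlation). Segment polarity genes rose in 6 of 8 cases and mesoderm genes in 8 of 14 (adjusted p = 0.32 and 0.522 with an estimated correlation), while 7 of 14 gap genes fell (adjusted p = 0.523 with an estimated correlation). The zygotic list rose in 337 and fell in 120 of 1134 cases (314 and 110 adjusted over the list alone, median 0.36, adjusted p = 0.523 with an estimated correlation). Against the batch1 controls its median was -0.49, bcd, gsb, hh and Ubx changed direction, and so did the medians of segment polarity (-0.44) and mesoderm genes (-0.50), whereas those of gap (-0.52), early zygotic (-0.28), maternal axis (-0.29) and maternal regulator genes (-0.05) stayed below 0. In all 4261 of 8236 genes changed (2259 rose, 2002 fell), and against the batch1 controls 2005 calls had the same and 214 the opposite direction.

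**Figure D4:**
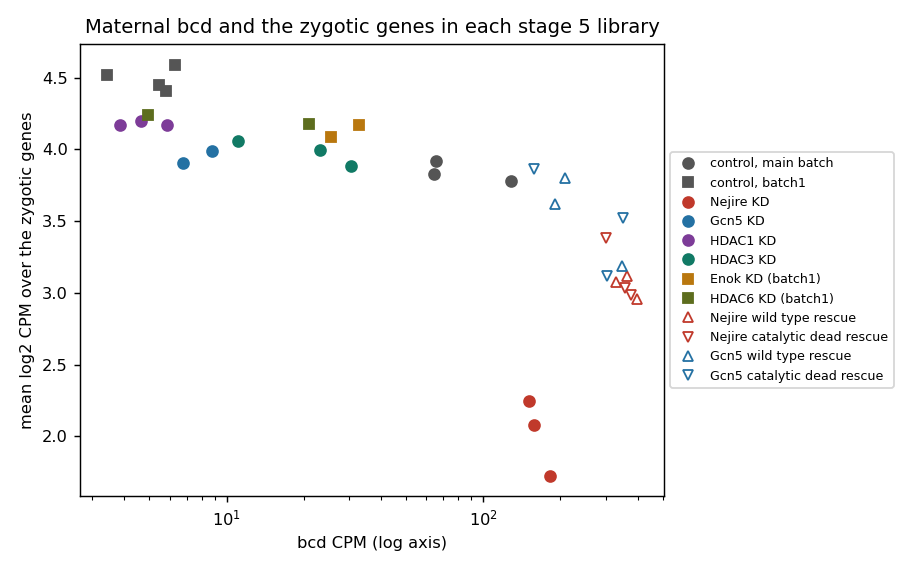
Mean log2 CPM of 755 zygotic genes against the level of bcd (CPM, log axis) in each stage 5 total RNA library (points, libraries; colours, groups). The batch1 controls (3.42 to 6.33 CPM of bcd) lie at higher zygotic levels than the main controls, and the Nejire knockdown libraries (152 to 182 CPM) the least.

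Between the Gcn5 rescues edgeR called 0 of 8140 genes, DESeq2 0, and 17 had an unadjusted p under 0.05, where chance gives 5% of genes, while another grouping of the same 6 libraries called 997. Gcn5 itself differed by 0.19 ± 0.14 (adjusted p = 1), and no list had a member that passed. Camera with the preset correlation called the zygotic list up (adjusted p = 0.0404, 0.877 with an estimated correlation), where its median was 0.01 and its mean -0.01. In simulated data of this design 98% of falls and 100% of rises of 2 log2 units were recovered, and 48% and 60% of those of 1 unit (50 genes each, of 7997).

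Nejire and Gcn5 knockdowns were then compared directly at stage 5. Their bcd levels were 164 and 7.77 CPM, and the difference had a correlation of -0.793 across genes with the axis of embryo age. ths (-3.93 ± 0.50), Antp (-4.74 ± 0.62), wg (-3.40 ± 0.48) and Mdr49 (-2.86 ± 0.43) were lower without Nejire. The follicle-cell gene Cp15 (-6.04 ± 1.32), Or2a (-7.55 ± 1.28) and the activin antagonist follistatin (Fs, -6.45 ± 1.16) were lower as well, while GluRIIB (6.81 ± 1.31), the forkhead gene fd19B (6.22 ± 1.05) and zormin (5.16 ± 0.97) were higher. All 11 pair-rule genes (median -2.43), 12 of 14 mesoderm and 7 of 8 segment polarity genes were lower (adjusted p = 0.0171 for each with an estimated correlation), and 16 of 18 maternal regulators higher (adjusted p = 0.149 with an estimated correlation). Over all genes 5268 differed, 2320 higher and 2948 lower without Nejire. Against the shared controls, the effects of both knockdowns had a correlation of -6.4e-04 and a covariance of -7.6e-04 across genes, where unchanged groups against the same controls gave 0.511 and 0.072 in 100 simulations. Of genes called in both, 493 moved the same way and 1318 opposite ways, and independent lists would share 363 up and 438 down.

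HDAC1 knockdown at stage 5 tested the loss of a deacetylase. The cell death genes rpr and grim rose, rpr from 12.8 ± 1.34 to 62.0 ± 8.05 CPM (2.26 ± 0.37, adjusted p = 5.2e-08) and grim, largely overlapped by noncoding genes, by 4.96 ± 1.00. fat-spondin, an extracellular matrix gene, rose by 5.07 ± 0.94, the carbon dioxide receptor Gr63a by 4.59 ± 0.98, the muscle myosin light chain Mlc2 by 3.83 ± 0.85 and the cilium gene BBS1 by 4.21 ± 0.84. hh rose from 5.28 ± 2.3 to 38.1 ± 7.43 CPM (2.98 ± 0.49) and gsb from 3.56 to 33.3 CPM; against the batch1 controls these log2 rises were 0.87 and 0.69. The small heat shock gene Hsp23 changed by -1.92 ± 0.26 and nullo by -6.92 ± 1.02. Of the apoptosis and p53 genes 7 of 14 rose and 4 fell (adjusted p = 0.17 with an estimated correlation). Ribosomal protein genes rose in 26 of 82 cases (15 adjusted over the list alone, adjusted p = 0.64 with an estimated correlation).

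In HDAC1 knockdown, bcd stood at 4.79 ± 1.02 CPM (n = 3), near the level of the batch1 controls. Segment polarity genes rose in 6 of 8 cases (median 1.62) and homeotic genes in 6 of 7 (median 1.65, Antp 1.83 ± 0.30), each with an adjusted p = 0.17 with an estimated correlation. Of the mesoderm genes 9 of 14 and of the neuroectoderm genes 9 of 14 rose (adjusted p = 0.251 and 0.245 with an estimated correlation). Against the batch1 controls htl, stumps, CadN, Meltrin, SoxN, en and Ubx, among others, turned lower. Early zygotic genes fell in 15 of 19 cases (median -1.44, adjusted p = 0.17 with an estimated correlation) and maternal regulators in 14 of 18 (0.245). The zygotic list rose in 453 and fell in 116 of 1134 cases (449 and 114 adjusted over the list alone, median 0.61, adjusted p = 0.251 with an estimated correlation), and its median against the batch1 controls was -0.24. Over all genes 4610 of 8236 changed (2264 rose, 2346 fell), and against the batch1 controls 2113 calls had the same and 195 the opposite direction. Scaled to the stable list the split was 3008 up and 1831 down, with all genes shifted by a median of 0.18 (Gcn5 knockdown: 0.13).

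HDAC3 knockdown at stage 5 tested the loss of a second deacetylase. The septate junction gene coracle (cora) rose from 4.98 ± 0.524 to 40.1 ± 4.68 CPM (2.99 ± 0.44, adjusted p = 1.8e-08), Sdb from 1.06 ± 0.155 to 34.3 ± 9.18 (5.05 ± 0.79), Cyp18a1 by 2.70 ± 0.50, the capsid-like gene Arc1 by 2.76 ± 0.52, rpr by 1.26 ± 0.28 and Hsp23 by 1.00 ± 0.17. The esterase alpha-Est1 fell from 57.1 ± 1.12 to 4.79 ± 0.774 CPM (-3.56 ± 0.49, adjusted p = 3.4e-09), hwt by -5.62 ± 0.95, nolo by -3.69 ± 0.62, tld by -0.77 ± 0.17 and Dhit, largely overlapped by an antisense gene, by -3.98 ± 0.58. These genes kept direction and call against the batch1 controls. Maternal genes, whose direction turned there, fell: osk by -2.54 ± 0.48, bcd by -1.96 ± 0.42 and smg by -1.79 ± 0.36. Of the maternal axis genes 13 of 17 and of the maternal regulators 11 of 18 fell (13 adjusted over the list alone; adjusted p = 0.348 for both with an estimated correlation). Dorsal ectoderm genes fell in 10 of 19 cases, and mesoderm genes rose in 6 of 14 (adjusted p = 0.348 for both with an estimated correlation). The zygotic list rose in 197 and fell in 61 of 1134 cases (171 and 51 adjusted over the list alone, median 0.25, adjusted p = 0.39 with an estimated correlation), against -0.54 with the batch1 controls. Over all genes 2867 of 8236 changed (1189 rose, 1678 fell). Against the batch1 controls 848 calls had the same and 559 the opposite direction.

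HDAC1 and HDAC3 knockdown embryos at stage 5 were compared directly. Their bcd levels were 4.79 and 21.6 CPM, and the difference had a correlation of 0.309 across genes with the axis of embryo age. C15 was higher without HDAC1 (6.82 ± 1.38), as were the homeobox gene ladybird early (lbe, 3.96 ± 0.90), gsb (2.90 ± 0.54), hh (2.26 ± 0.40) and fat-spondin (4.35 ± 0.83). Sdb (-5.07 ± 0.78), nullo (-4.80 ± 0.85), Cyp18a1 (-4.33 ± 0.68), corolla (-3.94 ± 0.55) and Hsp23 (-2.92 ± 0.36) were lower. Homeotic genes were higher in 7 of 7 cases (adjusted p = 0.229 with an estimated correlation) and early zygotic genes lower in 15 of 19 (0.13). In all 3387 of 8236 genes differed (1730 higher, 1657 lower without HDAC1). Measured from the shared controls, the effects of both had a correlation of 0.607 and a covariance of 0.553 across genes, against 0.548 and 0.0715 for unchanged groups. Of genes called in both, 2125 moved the same way and 83 opposite ways.

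At stage 2 the knockdowns act on an embryo that still runs on maternal RNA. Without Nejire, the adhesion genes kirre and roughest (rst) changed by -4.44 and -3.70 on the log2 scale, egr, a TNF ligand, by -2.74 ± 0.66 and Hsp23 by -0.95 ± 0.16. The stress factor Xrp1 rose by 1.87 ± 0.34, sallimus (sls), the titin homologue, by 5.83 ± 1.08 and zormin by 5.38 ± 0.89. Of 6916 genes, 700 changed (368 rose, 332 fell; 342 in all with only the 2 groups in the fit), and the zygotic list, measured in 96 genes, rose in 13 and fell in 1 (adjusted p = 0.335 with an estimated correlation). Most genes of this list are too low at stage 2 to be tested unless a knockdown raises them, which favours rises. Of the 83 members that pass the filter in the other knockdowns, a choice made after the data had been seen, 7 rose and 1 fell.

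Gcn5 knockdown changed more genes at stage 2: 2551 (1331 rose, 1220 fell). Xrp1 rose by 2.62 ± 0.41, head involution defective (hid), a cell death gene, by 1.88 ± 0.40, the chitin synthase kkv by 4.44 ± 0.82, the acetyltransferase gene mof by 0.98 ± 0.18 and the neuropeptide chaperone 7B2 by 5.44 ± 0.86. nrm changed by -5.31 ± 0.76, nej by -0.78 ± 0.29, enok by -0.69 ± 0.15 and Sin3A by -0.99 ± 0.22. Of 96 measured genes of the zygotic list 44 rose and 4 fell (median 1.02), but many are measured only because they are high in this knockdown. Of the 45 that pass the filter in the other knockdowns 13 rose and 3 fell (median 0.55, adjusted p = 0.108 with an estimated correlation). Ribosomal protein genes rose in 39 and fell in 4 of 81 cases (adjusted p = 0.784 with an estimated correlation), and over all genes the change ran against gene length (Spearman -0.287 across genes).

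HDAC3 knockdown at stage 2 was compared with the same controls. brinker (brk), the repressor of Dpp targets, rose from 0.127 ± 0.133 to 17.3 ± 1.95 CPM (7.47 ± 1.16), the JAK/STAT target Socs36E from 0.166 ± 0.0305 to 31.6 ± 1.13 (7.42 ± 0.95), kayak (kay, the fly Fos) by 3.05 ± 0.48, egr by 2.40 ± 0.44, hid by 2.17 ± 0.42 and Smr, an HDAC3 corepressor, by 1.36 ± 0.37. The chitinase gene Cht10 changed by -5.48 ± 0.85 and nrm by -8.36 ± 1.13. At stage 2 nrm stood between 0.058 and 0.50 CPM in every knockdown but that of Nejire (17.5 CPM). The main and batch1 controls had 20.5 and 13.6 CPM, so its fall is not particular to 1 enzyme. The neuroectoderm genes vn, brk and Meltrin rose, the last with an adjusted p = 0.0479 (2 passed under RLE scaling). brk is tested only because it is high in this knockdown, so no call of that list is given. Of 96 measured zygotic genes 24 rose and 3 fell, or 13 and 3 of the 69 that pass the filter in the other knockdowns (adjusted p = 0.51 with an estimated correlation). Also rising were the small heat shock genes Hsp23, Hsp26 and Hsp27. HDAC1 knockdown raised Arc1 (2.44 ± 0.53), Kebab (2.05 ± 0.34), HDAC11 (1.49 ± 0.49) and the corepressor CoRest (0.76 ± 0.12), and lowered nrm (-6.68 ± 1.01), kirre (-4.71 ± 0.73) and Hsp23 (-1.85 ± 0.25). There 1101 genes changed (603 rose, 498 fell), and without HDAC3 1218 (606 rose, 612 fell). With 1 library left out these counts ran from 585 (knockdown replicate 2) to 946 for HDAC1 and from 919 to 1071 for HDAC3. Ribosomal protein genes rose in 27 of 81 cases without HDAC1 (adjusted p = 0.78 with an estimated correlation; Spearman -0.218 of the change with gene length). Dscam4 had 0 counts in all stage 2 controls and stood at 14.2 CPM or more in each of the 6 knockdowns, at least 129.8-fold higher (without Nejire at least 255-fold), counting the controls at a floor of 3 counts over the group. Cyp4p2, also without counts in the controls, was at least 185-fold higher without Nejire.

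The change of each knockdown effect from stage 2 to stage 5 was tested as an interaction. zld fell without Nejire at stage 5 (-0.86) and was not called at stage 2 (0.32, adjusted p = 0.39 in the fit of that stage), a difference of -1.17 ± 0.40, and Xrp1 (-1.82 ± 0.35) and Diap1 (-1.29 ± 0.21) shared the direction, whereas bcd (0.92 ± 0.30) and twe (0.82 ± 0.25) went the other way. Inx3, D and dpp, also called, had 0 counts in the stage 2 controls. Without HDAC3, brk (-7.18 ± 0.94) and Socs36E (-6.89 ± 0.85) were raised at stage 2 and little changed at stage 5 (0.25 and 0.49). Without HDAC1, fat-spondin (7.25 ± 1.64) and srp (2.82 ± 0.75) rose more at stage 5, and Ldh (-6.21 ± 1.22) less. The stage 5 rise of srp turned to a fall against the batch1 controls. Across genes, the interactions of Nejire, Gcn5, HDAC1 and HDAC3 correlated at -0.546, 0.461, 0.593 and 0.453 with the axis of embryo age. Gcn5 itself fell less at stage 5 (6.88 ± 0.76), as did HDAC1 in its knockdown (5.63 ± 0.62). Of 8675 genes, the effect differed in 1745 for Nejire (770 up, 975 down), 2774 for Gcn5 (1185, 1589), 3245 for HDAC1 (1634, 1611) and 1974 for HDAC3 (697, 1277). Under RLE scaling the splits of Nejire, Gcn5 and HDAC3 were 331 up and 1460 down, 1884 and 1249, and 1376 and 1060, with median shifts of -0.17, 0.16 and 0.12.

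Enok knockdown was compared with the batch1 controls. At stage 5 bcd rose by 2.46 ± 0.65, swa by 1.31 ± 0.39 and Arc1 by 2.76 ± 0.58 (n = 2 and 4). Scaled over all total RNA libraries, bcd stood at 29.1 CPM against 5.25. Across genes the stage 5 effect correlated at -0.383 with the axis of embryo age, so age was not separated from loss of Enok. Arc1 rose in all 6 knockdowns at stage 5. ds changed by -2.97 ± 0.60, the homeobox gene Drop (Dr) by -2.16 ± 0.50, the EGFR ligand vein (vn) by -1.24 ± 0.32, abd-A by -1.24 ± 0.34 and RpL38 by -1.79 ± 0.57. The zygotic list fell in 70 and rose in 6 of 780 cases (155 and 15 adjusted over the list alone, median -0.33, adjusted p = 0.51 with an estimated correlation). At stage 2 the synaptonemal complex genes corolla (2.17 ± 0.37) and c(3)G (1.88 ± 0.38), Arc1 (2.75 ± 0.54) and Xrp1 (1.69 ± 0.38) rose, and nrm (-7.10 ± 1.56) and egr (-3.23 ± 1.03) fell (n = 2 and 3). In all 323 of 8162 genes changed at stage 5 (110 rose, 213 fell) and 358 of 6702 at stage 2 (145 rose, 213 fell). With 1 library left out the stage 5 count ran from 29 (knockdown replicate 2) to 522 (control replicate 3), and the stage 2 count from 202 to 315. The stage 5 count was also 47 with a replicate block, 170 with the 3 named controls, 602 with DESeq2, 746 with only the 2 groups and 912 without a filter of low counts, which gave 583 at stage 2.

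HDAC6 knockdown was compared with the same batch1 controls. At stage 5 Arc1 rose by 3.62 ± 0.68, y by 3.51 ± 0.68, the piRNA pathway gene piwi by 0.84 ± 0.21 and mof by 0.75 ± 0.17, whereas the homeobox gene cut (ct) changed by -1.88 ± 0.50, kek1 by -1.95 ± 0.48 and Xrp1 by -0.96 ± 0.25 (n = 2 and 4). At stage 2 Arc1 (4.13 ± 0.69) and Arc2 (2.12 ± 0.40) rose and nrm fell (-4.93 ± 1.17; n = 2 and 3). The zygotic list fell in 17 and rose in 1 of 780 cases at stage 5 (45 and 2 adjusted over the list alone, median -0.25, adjusted p = 0.596 with an estimated correlation). Across genes the stage 5 effect correlated at -0.249 with the axis of embryo age, so age was not separated from loss of HDAC6. In all 116 genes changed at stage 5 (68 rose, 48 fell; scaled to the stable list 40 and 47) and 212 at stage 2 (168 rose, 44 fell). With 1 library left out the stage 5 count ran from 46 (control replicate 2) to 344 (knockdown replicate 1), and the stage 2 count from 57 (knockdown replicate 1) to 174 (control replicate 1). At stage 5 a replicate block gave 15, the 2 groups alone and the 3 named controls 76 each, DESeq2 282 and no filter of low counts 549, or 370 at stage 2.

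The enzyme families and markers of other tissues were examined last. In Nejire knockdown at stage 5, 6 of 31 acetyltransferase and SAGA genes rose and 5 fell (median 0.06, mean -0.07), of the deacetylase genes 3 of 18 fell, and of the histone variant genes 1 rose and 1 fell of 6. Heat shock genes rose in 4 of 10 cases and fell in 2, late neural and muscle genes rose in 2 and fell in 1 of 4, and other late genes rose in 1 and fell in 4 of 9. Medians and test differed in sign for the deacetylase genes (median -0.06, camera upward) and the late neural and muscle genes (median 0.58, camera downward), neither of them called (adjusted p = 0.848 and 0.838). The stable list rose in 350 and fell in 250 of 1559 cases, with a median of 0.12 and a mean of -0.01. In Gcn5 knockdown 10 of 18 deacetylase genes fell. Fewer than 3 immune genes were measured in any comparison, so that list had no result. Chorion, vitelline and yolk genes and testis genes reached 3 measured members in nuclear RNA, and testis genes also in the interactions, where mia rose for Gcn5 (0.93 ± 0.26) and HDAC1 (2.66 ± 0.40).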

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

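The tests of explanations in this part were chosen after the results had been seen, except the splits of libraries, which were written before. 3 levels stood apart in the 4 stage 5 controls of batch1, where 25 measures were examined and chance sets apart about 1 in 20 groups. HDAC1 was at 730.8 CPM in replicate 1 and between 692.6 and 697.3 in the others (gap over range 0.877), enok at 551.8 in replicate 2 and between 413.1 and 435.4 in the others (0.840), and zld at 1739.7 in replicate 2 and between 951.1 and 1085 in the others (0.830), each above Dixon's 95% limit.

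The knockdown effect differed between stages, by a test of the interaction in edgeR, for 1745 genes with Nejire, 2774 with Gcn5, 3245 with HDAC1 and 1974 with HDAC3. Regrouping the libraries within stages called at least as many genes in 2 of 30 groupings for Nejire (highest other 2000), 4 of 30 for HDAC1 (highest other 3567) and 3 of 30 for HDAC3 (highest other 2063), the real grouping included. Each of these kept the real groups of stage 5, and the highest count among groupings that did not was 131, 93 and 102. These counts therefore rest on the stage 5 groups and leave open how stage 2 differs. Among the 35 groupings of the batch1 controls by stage, only the real one reached its count (6863, highest other 0). Every other grouping mixes both stages within at least 1 group, which widens the spread there and leaves few calls. As 1 of 35 is also the lowest possible outcome, this test cannot exclude chance.

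With 10 groupings of 3 against 3 libraries, the number is too small to tell chance. The real grouping was the 1 with most calls for the main controls by stage (5929, highest other 0), Nejire (3124 and 0 at stage 5, 700 and 3 at stage 2, 1248 and 0 in nuclear RNA), HDAC1 (4610 and 0, 1101 and 0), HDAC3 (2867 and 0, 1218 and 0), Gcn5 at stage 2 (2551 and 0), HDAC1 against HDAC3 (3387 and 0) and the Nejire rescues (21 and 0). For the Gcn5 rescues the real count was 0 and the highest other 997, which points to a structure among these 6 libraries apart from the protein. The stage 5 comparisons with Gcn5, and those with Enok and HDAC6, have groups of 2 and were not regrouped.

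Zygotic genes stood higher in Gcn5, HDAC1 and HDAC3 knockdown than in the main controls at stage 5. Across genes, the effects followed an axis of embryo age drawn from the 6 Gcn5 rescue libraries, with a lowest correlation of 0.62 (Gcn5), and the list turned lower against the batch1 controls, which held less bcd RNA. Older embryos in these knockdown libraries could therefore account for the rise. A rise of zygotic RNA from another cause would follow this axis as well, so the correlation alone cannot decide for age. The axis measures age imperfectly, as it correlated at 0.483 (main) and 0.642 (batch1) with the change of controls from stage 2 to 5. Mean log2 CPM of 1573 cleared genes was 3.82 to 3.91 without Gcn5 or HDAC1, within the main controls (3.64 to 4.07). Without HDAC3 it was 3.45 to 3.70. Scaling to the stable list moved all genes by a median of 0.126 for Gcn5 and 0.177 for HDAC1 and left list medians of at least 0.49, above the main values, which argues against scaling as the whole cause there. For HDAC3 it moved genes by only 0.0548 (list median 0.30), so scaling stays open, as does a true effect of all 3 enzymes, since age was not recorded within stage 5 and the batch1 controls belong to another set.

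Zygotic genes stood lower in Nejire knockdown, in total and in nuclear RNA. Younger embryos could account for it, as the effects ran against the axis of embryo age, with correlations of -0.597 and -0.682 across genes. A loss of zygotic RNA from another cause would run against this axis as well, so these correlations cannot decide for age. All 6 of 6 Nejire rescue libraries had at least as much bcd RNA as the knockdown (300 to 398 against 152 to 182 CPM). Their lowest zygotic level was 0.71 above the knockdown's highest on the log2 scale. Both groups held more bcd than the main stage 2 controls (134 CPM, scaled within that stage), so bcd cannot rank them by age. Mean log2 CPM of cleared genes was 3.93 to 3.97 in the knockdown, within the main controls (3.64 to 4.07). The rescues belong to another set and other parent lines, so age stays open, as does a true effect of Nejire. Uneven ERCC recovery is excluded for the nuclear fall, as the median nearest 0 under TMM on fly genes or without knockdown replicate 3 was -2.20. It fits the small nuclear count of genes, which rose to at least 5626 under either change.

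Dscam4 was higher in all 6 knockdowns than in the total RNA controls at both stages. Within the nuclear set Dscam4 differed by -0.075 (± 0.22) between Nejire knockdown and controls that keep Nejire, against 5.42 in total RNA. The library names give these controls as another line, whose Dscam4 level may be its own. The nuclear value therefore cannot decide on loss of Nejire. No such comparison exists for the other 5 knockdowns. The lowest wild type Gcn5 rescue library had 44.1 CPM and the highest stage 5 control 2.3, but in another set. The nuclear controls, named wild type in the library names, held 23.5 to 27.8 CPM under TMM on fly genes, thus without any knockdown. As nuclear RNA of another line they cannot settle total RNA, so loss of Nejire or of the other enzymes stays open. Dscam4 was kept after other shared genes were seen to change in nuclear RNA (of 15, 9 were called the same way and 2 the opposite way under TMM on fly genes), so the nuclear value cannot decide for a difference between lines. That difference and an effect of the control line's own hairpin stay open.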

How the results depend on the processing

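Of the named genes under all settings, 12308 results kept direction and call, 734 kept direction but no longer passed and 94 turned, all of the latter against the batch1 controls, a setting chosen after the data had been seen. The batch1 controls lie in another set, so age and set cannot be told apart there. RLE and list limits changed the call of no zygotic list. Limits include the choice of control set, the parent line, which differed between each knockdown and its controls, and the 2 or 3 libraries per group. Others are the depth of 2.45 M counts in the smallest library and the uneven ERCC share of the nuclear libraries. The cause was not tested for any change below, except that fewer libraries or genes were used where the setting says so.

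Against the batch1 controls 6027 genes were called for Nejire knockdown, and the median of the zygotic list turned to -0.49 for Gcn5, -0.24 for HDAC1 and -0.54 for HDAC3, a list chosen on these same controls, and to -0.52, -0.29 and -0.45 with the list of the main set. Genes that turned, by log2 change there, were sc 0.31 for Nejire. For Gcn5 these turned higher: fd19B 0.064, bcd 0.53, twe 0.20, BigH1 0.086, gcl 0.13, Hsp27 0.55, Hsp26 0.044, crq 0.071, nanos 0.18, and these lower: Dark -0.052, slp2 -0.11, abd-A -0.72, Meltrin -0.85, wg -0.39, prd -0.34, Antp -0.68, ths -0.35, sob -0.040, CadN -0.61, gcm -0.057, drm -0.067, if -0.51, Abd-B -0.76, mid -0.61, Ubx -0.34, en -0.48, hh -0.17, gsb -0.17. For HDAC1 these turned higher: Hsp27 0.29, gcl 0.51, zen 0.12, Hsp26 0.021, nanos 0.11, and these lower: SoxN -0.44, elav -0.43, knrl -0.073, srp -0.53, drm -0.33, htl -0.43, gcm -0.15, ush -0.60, stumps -0.21, if -0.35, CadN -0.19, Ubx -0.27, Meltrin -0.031, mid -0.20, en -0.29. For HDAC3 these turned higher: osk 0.18, nullo 2.76, amos 1.43, bcd 2.09, swa 1.10, BicD 0.57, smg 0.78, otu 0.54, armi 0.18, gcl 0.57, scw 0.90, sc 0.92, BigH1 1.10, tor 0.13, zen 0.51, crq 0.40, vret 0.44, Hat1 0.41, DnaJ-1 0.14, nanos 0.15, Hsc70-3 0.012, Hsp83 0.013, hb 0.58, Tip60 0.0064, ebi 0.053, and these lower: prd -0.78, wg -0.78, nkd -0.60, slp2 -0.11, srp -0.89, abd-A -0.78, CadN -1.08, wntD -0.42, Ku80 -0.23, knrl -0.25, hh -1.38, Antp -0.92, Ubx -1.08, cid -0.031, ths -0.57, elav -0.34, Meltrin -0.71, drm -0.37, SoxN -0.22, pyr -0.16.

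At stage 2, with the members of the zygotic list that pass the filter in the other knockdowns, chosen after the data had been seen, the list no longer passed for Nejire (0.21, adjusted p = 0.326) and HDAC3 (0.22, adjusted p = 0.185), since members measured through their own rise were left out, and passed for Gcn5 with a smaller median (0.55, adjusted p = 0.0155). With an estimated correlation the zygotic list no longer passed for Gcn5 (0.36, adjusted p = 0.523), HDAC1 (0.61, adjusted p = 0.251), HDAC3 (0.25, adjusted p = 0.39), Enok (-0.33, adjusted p = 0.51), HDAC6 (-0.25, adjusted p = 0.596) and nuclear RNA (-2.40, adjusted p = 0.608). Without a filter of low counts 912 genes were called for Enok at stage 5 and 583 at stage 2, 549 and 370 for HDAC6, and 478 between the Nejire rescues. With only the 2 groups in the fit the counts were 342 for Nejire at stage 2, 746 for Enok and 76 for HDAC6 at stage 5, and with only the 3 named controls 170 and 76. DESeq2 called 602 genes for Enok and 282 for HDAC6 at stage 5, and 88 between the Nejire rescues. TMM on fly genes called 5626 nuclear genes.

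Same replicate numbers were not taken as pairs, as no set had every same-numbered pair of libraries correlate over 0.1. In the main set 3 of 26 pairs did at stage 5 and 5 of 30 at stage 2, in batch1 0 of 6 and 5 of 6 (2 of 10 and 7 of 8 by the numbers in library names), in nuclear RNA 2 of 3, in the Nejire rescues 0 of 3 and in the Gcn5 rescues 2 of 3. Best with their own number correlated 5 of 14 libraries of the main set at stage 5, 4 of 15 at stage 2, 0 of 6 and 5 of 6 of batch1 (4 of 8 and 7 of 7 by the numbers in library names), 4 of 6 of nuclear RNA, 0 of 6 of the Nejire rescues and 4 of 6 of the Gcn5 rescues, so batch1 at stage 2 came close to pairs. In batch1 at stage 2 the medians were 0.17 for the same and -0.148 for other numbers, and in the Gcn5 rescues 0.643 and 0.0732. With a replicate block the counts were 47 for Enok and 15 for HDAC6 at stage 5, 716 in nuclear RNA and 9 between the Nejire rescues, and the other counts stayed within 1.5 times.

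With each library left out in turn, counts ran from 5579 to 6445 for the main controls and 6627 to 6938 for batch1 by stage. At stage 5 they ran from 2584 to 3367 for Nejire, 3151 to 4218 for Gcn5, 4054 to 4537 for HDAC1, 2082 to 2998 for HDAC3, 29 to 522 for Enok and 46 to 344 for HDAC6. At stage 2 they ran from 476 to 790, 1887 to 2418, 585 to 946, 919 to 1071, 202 to 315 and 57 to 174 in the same order. They ran from 548 to 7272 in nuclear RNA, 7 to 145 between the Nejire rescues, 0 to 0 between those of Gcn5, 4616 to 5034 for Nejire against Gcn5 and 2432 to 3056 for HDAC1 against HDAC3. A group left with 1 library is assumed to vary like the others.

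Single libraries moved these counts by over 1.5 times. For HDAC1 at stage 2 the count was 585 without knockdown replicate 2 and 652 without control replicate 2. Enok at stage 5 gave 48 without knockdown replicate 1, 29 without knockdown replicate 2, 161 without control replicate 1, 167 without control replicate 2, 522 without control replicate 3 and 170 without control replicate 4. Enok at stage 2 gave 202 without knockdown replicate 1 and 238 without control replicate 2. For HDAC6 at stage 5 there were 344 without knockdown replicate 1, 262 without knockdown replicate 2, 61 without control replicate 1, 46 without control replicate 2, 212 without control replicate 3 and 76 without control replicate 4. HDAC6 at stage 2 gave 57 without knockdown replicate 1, 132 without knockdown replicate 2, 122 without control replicate 2 and 139 without control replicate 3. In nuclear RNA there were 801 without knockdown replicate 2, 7272 without knockdown replicate 3, 548 without control replicate 1, 560 without control replicate 2 and 593 without control replicate 3. Between the Nejire rescues there were 10 without wild type replicate 1, 7 without wild type replicate 2, 9 without wild type replicate 3, 145 without catalytic dead replicate 1, 130 without catalytic dead replicate 2 and 8 without catalytic dead replicate 3. The median of the zygotic list ran from -1.78 to -1.48 for Nejire, -3.61 to -1.97 in nuclear RNA (the lower without knockdown replicate 3), 0.27 to 0.40 for Gcn5, 0.58 to 0.65 for HDAC1, 0.22 to 0.38 for HDAC3, -0.38 to -0.28 for Enok and -0.32 to -0.19 for HDAC6. Without Gcn5KD replicate 1 the list no longer passed for Gcn5 (0.27, adjusted p = 0.0725 by camera of limma).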

Other observations

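The genes that changed the same way in all 6 knockdowns were counted after the single comparisons had been seen. At stage 2, vimar, CG32373, His2B:CG33868, Dscam4 and squ rose and CG3328, CG31997, Cadps and mgl fell in all 6. Independent lists would share 0.273 genes, against these 9, though 4 knockdowns share 1 set of controls and 2 the other. By the library names both control sets come from the same cross. A trait of that line would enter all 6 comparisons, so 0.273 is not a chance level. At stage 5, Arc1 and Dscam4 rose and CG8209, Rpi, nolo, CG31997, CG31999, mgl and CG9932 fell in all 6. These genes number 15 over both stages, 3 of them at both.

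In nuclear RNA, scaled by TMM on fly genes, Dscam4 differed by -0.07 ± 0.22 between Nejire knockdown and control (adjusted p = 0.786), and with ERCC scaling by -0.14 ± 0.76. bcd stood at 29.1 CPM in Enok knockdown, 12.9 in HDAC6 knockdown, 21.6 in HDAC3 knockdown, 364 and 344 in the wild type and catalytic dead Nejire rescues, and 249 and 271 in those of Gcn5, at stage 5. The correlation of effects with the age axis across genes was 0.646 for HDAC1, 0.629 for HDAC3, -0.383 for Enok and -0.249 for HDAC6. At stage 2 the slope of log2 CPM per doubling of gene length differed by -0.105 between Gcn5 knockdown and control, where the wider range within these 2 groups was 0.141. At stage 5 the slopes were -0.0597 and -0.211 in Gcn5 knockdown and 0.27, 0.0713 and 0.0197 in the controls. The Spearman correlation of log2 change with gene length across genes was -0.329 for Gcn5, -0.305 for HDAC3, -0.175 for HDAC1 and -0.102 for Nejire at stage 5, and -0.287, 0.115, -0.218 and 0.257 at stage 2.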
